A study of Mus musculus with 7 samples.

How the data were processed

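RNA was measured in placentas of BALB/c females mated with BALB/c males, an inbred mouse strain, so mother and fetus share one genetic background. Per the labels, 3 pregnancies received saline and 4 received Escherichia coli lipopolysaccharide (LPS), a bacterial cell wall component used here to bring on preterm labor, injected into the upper right uterine horn. The series' design text counts the samples as separate pregnancies, so each library is 1 replicate. The labels' protocols place the injection on gestation day 15.5 and the collection 6 hours after LPS, while the sample characteristics name day 13.5. The day is left open here, and both groups carry the same day in each source. The LPS group is labelled as preterm labor, and no collection time after saline is recorded here.

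The deposited table holds 1 value per gene and library for 25307 genes and 7 libraries, with an Ensembl gene identifier, a symbol and a position for each gene. No unit is stated in the sources used here. The values behave as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) made by the authors: they are not whole, the column sums differ between 479621 and 680820, and the lowest values of a gene scale with its transcript length in steps that are constant within a library. Per the submitters' processing notes, the reads were aligned with TopHat2 2.0.9 and the named genome build is mm8. The positions in the table are those of a later build: 25200 of the 25206 identifiers shared with the GENCODE M21 annotation of GRCm38 overlap its position for the same gene, and 13318 match it exactly. Coordinates given here are therefore those of the GRCm38 annotation for the identifiers in the table. The quantification program, the gene annotation, the strandedness of the libraries and the filters are not given in the sources used here. No gene in the table is at 0 in all 7 libraries. Genes with near-identical copies, such as the globins, the Prl2c prolactins and the mitochondrial genes with nuclear copies, may share reads in a way that cannot be checked from FPKM.

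FPKM values are not counts, so no count model was used. From the size of the smallest step in genes with a single annotated transcript of at least 2000 bases, the library depths come, in units of 1e6 reads, to about 17.4, 17.4 and 16.9 for saline 1 to 3 and 14.7, 19.4, 16.9 and 17.4 for LPS 1 to 4. At these depths 1 read on a transcript of 1 kilobase is worth between 0.0517 and 0.0682 FPKM. No counting interval is given, because the counts themselves were not recovered.

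The main test was fixed before the data were examined, as were the lists and the rule for named genes. For a table without counts it was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), over the 12454 genes with at least 1 FPKM in at least 3 libraries, with LPS against saline as the sole term and all 7 libraries. A gene can meet this filter through 1 group alone, so members high in 1 group are kept over members low in both. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors of fold changes are limma standard errors, and errors of FPKM means are SDs over 3 saline and 4 LPS libraries. A total of 42 gene lists (pathways, cell type markers, mitochondrial transcripts and fetal sex transcripts) was fixed in advance, and 600 of their 613 entries were found in the table. Lists with at least 3 tested members were tested with limma's camera (two-sided, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The fetal sex list was not tested. Camera with an estimated correlation and the rotation test fry served as alternatives. Library spread was described with principal components and Pearson correlations of log2(FPKM + 1).

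The genes named in the text follow a rule fixed in advance. They are the 10 largest increases and 10 largest decreases among changed genes whose groups do not overlap and whose higher group mean is at least 5 FPKM, with predicted genes skipped. To these come, from each list, up to 3 changed members with the smallest adjusted p, or the 2 with the highest level where none changed, and 20 genes named in advance (cytokines, labor-associated genes and trophoblast markers). Genes named outside the rule are marked as chosen after their values were seen.

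The alternatives planned in advance were median-ratio rescaling, quantile normalization, no low-value filter, a filter at 5 FPKM, leaving out each library, the replicate number as a block, limma without the trend, robust eBayes, pseudocounts of 0.1 and 0.01, library weights, stricter thresholds, lists without genes shared between lists and principal components of the 1000 most variable genes. After the data were seen, 4 fits were added: without saline 2 and saline 3, with the mean of the decidual stromal markers as a covariate, with a smooth trend on transcript length and GC content removed from each library, and with the presence of Y-linked transcripts as a covariate. The principal components without each library were also added then. Length and GC content came from the GENCODE M21 transcripts and were available for 12435 of the tested genes. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

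The steps were tested on simulated data of the comparison, with 12454 genes of which 200 were changed. The changed genes were drawn only from those with a mean level above about 5 FPKM. The limma fit called 58% of the genes changed 2-fold and 99% of those changed 4-fold, and 9 of its calls (5.42%) were unchanged genes. Camera called 5 of 5 moved lists and 0 unmoved ones of 40 simulated lists, fry called the 5 and 1 unmoved list. The simulated genes were drawn independently and the lists at random, so genes of a list did not move together. In the real lists the estimated correlation between members reached 0.84 (mitochondrial transcripts) and 0.97 (yolk sac markers). The simulated error rates therefore do not carry over to lists of correlated genes. The simulated libraries also lacked the spread, shared by many genes, that parted the real saline libraries. The recovery and error rates for genes therefore need not hold for the real fit, least of all for genes with low values. A simulated length trend gave a Spearman correlation of 0.759 between fold change and length, which the trend removal brought to -0.002.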

Results

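Placental RNA was sequenced from 3 pregnancies injected with saline and 4 injected with LPS to model inflammation-induced preterm labor in the mouse. Gene levels are FPKM values for 25307 genes. Between 11856 and 12455 genes reached 1 FPKM in a library. Fold changes are given on the log2(FPKM + 1) scale, which understates changes of genes with low values. The design holds 1 comparison, LPS against saline, in which LPS exposure and preterm labor go together.

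The neutrophil chemokine genes Cxcl1 and Cxcl2, the leukocyte adhesion genes Madcam1 and Icam1 and the signalling feedback genes Nfkbia and Socs3 rose in LPS placentas. The adult globin genes Hba-a1 and Hba-a2 and the steroid synthesis gene Star fell. Madcam1, an adhesion molecule that binds lymphocyte integrins, rose from 0.137 ± 0.0692 to 8.01 ± 1.03 FPKM (mean ± SD, n = 3 and 4). The neutrophil chemokine gene Cxcl1 rose 5.52-fold, from 8.58 ± 4.42 to 47.4 ± 11.5 FPKM, and the leukocyte adhesion gene Icam1 5.46-fold, from 5.9 ± 1.4 to 32.2 ± 7.47 FPKM. Star, which carries cholesterol into mitochondria for steroid synthesis, fell from 21.9 ± 3.98 to 9.24 ± 0.332 FPKM. In all, 459 genes were higher and 167 lower among 12454 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 193 and 32 of them changed at least 2-fold. Genes that were higher made up 73.3% of the changed genes, and 60.3% with quantile normalization (664 higher, 438 lower). The direction went with transcript length: 186 were higher and 10 lower among genes of at least 4635 bases. Among genes of up to 1992.5 bases, 33 were higher and 106 lower. With a length and GC trend removed, chosen after seeing the data, 377 were higher and 94 lower. Of these, 300 and 54 were shared with the 459 and 167. The total of 626 depended on single libraries: it was 3296 without saline 1, 64 without saline 2, 111 without saline 3, and 34, 186, 93 and 94 without LPS 1, 2, 3 and 4, while 31 genes passed in each of these 7 fits. With saline 2 and saline 3 left out, a fit chosen after seeing the data, 17 genes were higher and 12 lower, of which 16 and 2 were shared with the 459 and 167; that fit takes its spread from the LPS libraries and assumes that the lone saline library varies like them.

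The 10 largest increases began with Madcam1 (ENSMUSG00000020310, chromosome 10, 79664559 to 79668537, plus strand), at a log2 change of 2.98 ± 0.16 (SE; limma adjusted p 9.8e-05). By the rule that picked them, each lay above every saline library in every LPS library. Crispld2, a secreted LPS-binding protein gene (ENSMUSG00000031825, chromosome 8, 119992438 to 120052793, plus strand), changed by 2.52 ± 0.35, and Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115, plus strand) by 2.40 ± 0.28. Timp3, an inhibitor of matrix metalloproteinases (ENSMUSG00000020044, chromosome 10, 86300372 to 86349506, plus strand), changed by 2.30 ± 0.22, and Icam1 (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817, plus strand) by 2.26 ± 0.21. The immediate early transcription factor gene Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand) changed by 2.22 ± 0.28. The adenosine receptor gene Adora2b (ENSMUSG00000018500, chromosome 11, 62248984 to 62266453, plus strand) changed by 2.13 ± 0.17, from 1.98 ± 0.361 to 12.1 ± 1.68 FPKM. S100a9, a calcium-binding protein of neutrophils and monocytes (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, minus strand), changed by 2.10 ± 0.33. The guanylate-binding protein gene Gbp3 (ENSMUSG00000028268, chromosome 3, 142560026 to 142573209, plus strand) and Pfkfb3, which makes an activator of glycolysis (ENSMUSG00000026773, chromosome 2, 11471433 to 11554077, minus strand), changed by 1.93 ± 0.22 and 1.93 ± 0.21. The adjusted p of these 10 lay between 9.8e-05 and 0.016. Of them, Madcam1, Cxcl1, Timp3, Icam1, Egr1, Adora2b, Gbp3 and Pfkfb3 passed with each library left out, and Crispld2 and S100a9 did not.

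**Figure D1:**
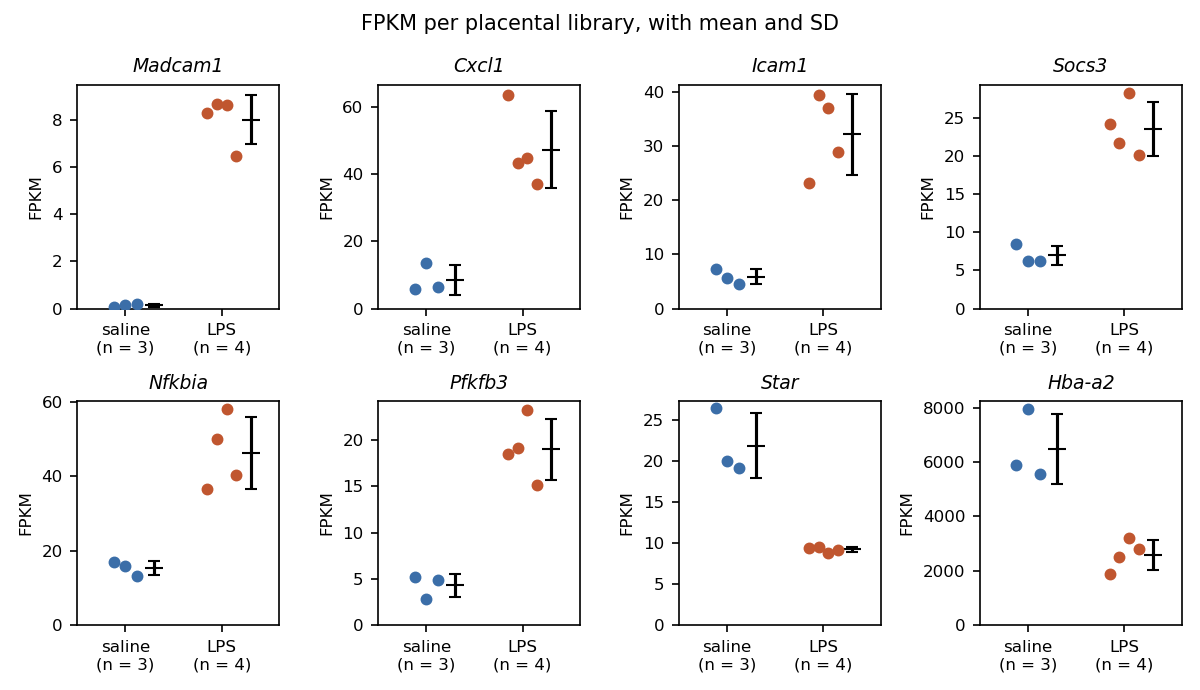
FPKM (linear vertical axes) of 8 genes in each placental library, saline in blue (n = 3) and LPS in orange (n = 4), with the mean and SD in black beside the points. No LPS library overlaps a saline library in any panel: Madcam1 lies at 6.47 to 8.65 in LPS and at 0.0695 to 0.208 in saline, and Star at 8.81 to 9.54 in LPS and 19.2 to 26.5 in saline. The rule that picked Madcam1, Cxcl1, Icam1, Pfkfb3, Star and Hba-a2 as largest changes required this.

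The 10 largest decreases were led by the macrophage elastase gene Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand), from 36.7 ± 11 to 11.8 ± 4.68 FPKM, and the collagenase gene Mmp1a (ENSMUSG00000043089, chromosome 9, 7464141 to 7476869, plus strand), from 37.5 ± 24.2 to 10.7 ± 3.22 FPKM. Snca, the alpha-synuclein gene that red cell precursors also express (ENSMUSG00000025889, chromosome 6, 60731575 to 60829855, minus strand), fell from 23 ± 3.64 to 8.42 ± 2.28 FPKM. Star (ENSMUSG00000031574, chromosome 8, 25806555 to 25815982, plus strand) changed by -1.15 ± 0.15 (SE; limma adjusted p 0.00851), and Cts3, a placental cathepsin gene (ENSMUSG00000074870, chromosome 13, 61564630 to 61570127, minus strand), by -1.15 ± 0.26. The adult alpha-globin genes Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298, plus strand) and Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465, plus strand) changed by -1.33 ± 0.25 and -1.15 ± 0.24; they are near-identical copies, so their reads may be shared. The remaining decreases were Aard (ENSMUSG00000068522, chromosome 15, 52040107 to 52045722, plus strand) at -1.34 ± 0.32, the inositol kinase gene Itpka (ENSMUSG00000027296, chromosome 2, 119742337 to 119751263, plus strand) at -1.16 ± 0.25 and Tex30 (ENSMUSG00000026049, chromosome 1, 44086613 to 44102441, minus strand) at -1.14 ± 0.20. The adjusted p of the 10 lay between 0.00851 and 0.0478, and Star alone among them passed with each library left out.

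Several genes that restrain NF-kB and cytokine signalling rose. Of 15 tested anti-inflammatory and feedback mediators, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 change of 1.13 (camera adjusted p 7.6e-07, adjusted p 0.355 with an estimated correlation). Socs3, a suppressor of cytokine receptors, rose from 7.0 ± 1.25 to 23.6 ± 3.56 FPKM, and Nfkbia, the NF-kB inhibitor, from 15.3 ± 1.98 to 46.2 ± 9.73 FPKM. Birc3, an inhibitor of apoptosis, rose from 10.9 ± 0.322 to 33.9 ± 6.75 FPKM. Il10 was listed at 0 in 6 of the 7 libraries and at 0.0854 FPKM in LPS 3. No list that passed camera kept its call with an estimated correlation. Against saline 1 alone 1 of the 15 feedback genes passed, with a median of 0.73 (camera adjusted p 4.4e-05), and the list mean was 3.37, 2.87 and 2.71 in saline 1, 2 and 3.

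Of 3 tested neutrophil-attracting CXC chemokines, Cxcl1 and Cxcl2 rose (2 adjusted over the list alone), with a list median of 1.83 (camera adjusted p 0.0072, adjusted p 0.355 with an estimated correlation). Cxcl2 was at 0.267 ± 0.272 FPKM in saline and 3.55 ± 1.18 in LPS. Of 4 tested proinflammatory cytokines 3 rose (3 adjusted over the list alone), with a median of 0.98 (camera adjusted p 0.0163, adjusted p 0.355 with an estimated correlation). Il1b rose from 0.689 ± 0.414 to 2.35 ± 0.532 FPKM, and the colony-stimulating factor genes Csf1 and Csf3, which drive macrophage and neutrophil production, rose from 3.87 ± 1.95 to 11.4 ± 2.06 FPKM and from 0.0837 ± 0.0421 to 1.16 ± 0.54 FPKM. Tnf and Il6 stayed under the filter of 1 FPKM in 3 libraries and were not tested. Tnf was at 0.256 ± 0.176 FPKM in saline and 0.671 ± 0.166 in LPS, and Il6 at 0.223 ± 0.142 FPKM in saline and 0.262 ± 0.142 in LPS. Csf3 and Cxcl2 stayed under 1 FPKM in every saline library, and Il1b reached it in saline 2 alone among them. All of these met the filter through LPS libraries, so the counts and medians can lean toward members high in LPS. The cytokine call ended without saline 3 (adjusted p 0.0619), LPS 1 (0.0523) or LPS 2 (0.117), and with no low-value filter (0.0979).

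None of 5 tested CC chemokines passed (0 adjusted over the list alone, camera adjusted p 0.707): Ccl2 was at 3.51 ± 2.36 FPKM in saline and 2.33 ± 0.492 in LPS, and Ccl6 at 6.86 ± 10 FPKM in saline and 4.37 ± 2.72 in LPS, with 18.4 FPKM in saline 1. Camera called the list lower against saline 1 alone (adjusted p 0.000781) and with the decidual marker mean as a covariate (0.0040).

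Several adhesion and immediate early genes rose. Of 8 tested leukocyte adhesion genes, Madcam1, Icam1 and Vcam1 rose (4 adjusted over the list alone), with a median of 0.63 (camera adjusted p 0.0093, adjusted p 0.355 with an estimated correlation). Vcam1 rose from 2.76 ± 0.281 to 5.87 ± 1.42 FPKM. The adhesion call ended against saline 1 alone (adjusted p 0.0698), in the fit whose spread comes from the LPS libraries only. Of 15 immediate early genes 6 rose (10 adjusted over the list alone), with a median of 0.69 (camera adjusted p 1.2e-05, adjusted p 0.521 with an estimated correlation). Junb rose from 14.2 ± 6.21 to 46.6 ± 5.69 FPKM, Fos from 9.42 ± 5.02 to 35.1 ± 6.66 FPKM and Egr1 from 1.68 ± 1.04 to 11.3 ± 3.48 FPKM. Of the immediate early genes 0 passed against saline 1 alone, with a median of 0.54 (camera adjusted p 0.00104), and 3 with the decidual covariate, with a median of 0.61 (0.000158). The list mean was 3.56, 2.91 and 2.91 in saline 1, 2 and 3 and 3.79 to 4.17 in LPS.

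Some interferon-inducible genes rose. Of 14 tested interferon-gamma-inducible genes 4 rose (7 adjusted over the list alone), with a median of 0.45 (camera adjusted p 0.00091, adjusted p 0.355 with an estimated correlation). Gbp3 rose 4.28-fold, Gbp5 from 0.356 ± 0.171 to 2.11 ± 0.41 FPKM and Gbp2 from 5.4 ± 1.42 to 10.2 ± 1.12 FPKM. Cxcl10 did not pass (limma adjusted p 0.062), at 0.429 ± 0.161 FPKM in saline and 1.38 ± 0.53 in LPS. Of 22 type I interferon-stimulated genes, Ddx58, a sensor of viral RNA, and the signal transducer Stat2 rose (9 adjusted over the list alone), with a median of 0.49 (camera adjusted p 0.0072, adjusted p 0.666 with an estimated correlation). Ddx58 rose from 16.1 ± 2.06 to 30.1 ± 6.55 FPKM and Stat2 from 7.26 ± 2.74 to 15.1 ± 2.87 FPKM. This call ended against saline 1 alone (adjusted p 0.0749, median 0.24) and with fry (0.086).

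Genes of hypoxia response and glycolysis rose in 6 of 17 tested cases (14 adjusted over the list alone), with a median of 0.65 (camera adjusted p 1.1e-05, adjusted p 0.355 with an estimated correlation). Ndrg1, a stress-responsive gene, rose from 241 ± 55.7 to 476 ± 70.9 FPKM, the phosphofructokinase gene Pfkl from 11.8 ± 2.39 to 21.8 ± 3.16 FPKM, and Pfkfb3 from 4.3 ± 1.28 to 19 ± 3.33 FPKM. The median was 0.38 against saline 1 alone and 0.42 with the decidual covariate, each with 1 gene past the threshold (camera adjusted p 0.000538 and 1.5e-05), and the list mean was 5.75, 5.19 and 5.16 in saline 1, 2 and 3 and 5.98 to 6.16 in LPS.

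Placental nutrient transporter genes rose in part. Of 19 placental nutrient transporters 4 rose (4 adjusted over the list alone), with a median of 0.45 (camera adjusted p 0.0081, adjusted p 0.666 with an estimated correlation). Slc43a2, an amino acid transporter, rose from 9.56 ± 3.03 to 26 ± 4.75 FPKM, and the glucose transporter genes Slc2a1 and Slc2a3 rose from 382 ± 47 to 619.6 ± 57.6 FPKM and from 18 ± 4.33 to 35.2 ± 7.42 FPKM. The transporter call ended with fry (adjusted p 0.0885). Against saline 1 alone 0 transporter genes passed, with a median of 0.24 (camera adjusted p 0.0109), and with the decidual covariate 0 passed, with a median of 0.35 (0.00524).

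Matrix metalloproteinases and their inhibitors went both ways. Of 14 tested, Timp3 and the aggrecanase gene Adamts4 rose and 2 members, Mmp12 among them, fell (7 and 2 adjusted over the list alone). Adamts4 rose from 5.21 ± 1.27 to 20.6 ± 2.56 FPKM. The list median was 0.74 (camera adjusted p 0.026, adjusted p 0.693 with an estimated correlation), and -0.20 against saline 1 alone (adjusted p 0.994). The call also ended without saline 3 (0.167), LPS 2 (0.117) or LPS 4 (0.103), with the decidual marker mean as a covariate (0.283), with the Y-linked covariate (0.0508) and with fry (0.138). The mean of the list was 3.58, 2.56 and 2.39 in saline 1, 2 and 3 and 3.21 to 3.66 in LPS on the log2(FPKM + 1) scale, and that of the decidual stromal markers 4.70, 3.29 and 3.10 against 4.04 to 4.50.

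Some erythroid markers, adult globins among them, fell. Of 10 tested, 4 were lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.90 (camera adjusted p 1.4e-05, adjusted p 0.355 with an estimated correlation). Hba-a2 fell from 6477 ± 1289 to 2589 ± 551 FPKM, Hba-a1 from 6335 ± 1300 to 2851 ± 510.5 FPKM, and Alas2, which starts heme synthesis in red cell precursors, from 66.7 ± 12.3 to 33.7 ± 10.4 FPKM. Mitochondrially encoded transcripts fell in 6 of 13 cases (13 adjusted over the list alone), with a median of -0.76 (camera adjusted p 6.2e-10, adjusted p 0.369 with an estimated correlation). The respiratory complex I genes mt-Nd3, mt-Nd6 and mt-Nd4l fell from 813 ± 166 to 374 ± 72.4 FPKM, from 851 ± 198 to 406 ± 61.7 FPKM and from 327 ± 99.8 to 168 ± 7.36 FPKM. Across genes, which are not independent replicates, the log2 change correlated with transcript length (Spearman's rho 0.44 over 12435 genes): genes of up to 1992.5 bases had a median of -0.21 and those of at least 4635 bases 0.29. With a length and GC trend removed from each library, the mitochondrial median was -0.05 (camera adjusted p 0.293) and the erythroid median -0.78 (6.4e-05). Against saline 1 alone 0 mitochondrial and 0 erythroid genes passed, with medians of -0.43 and -0.86, and camera called both lists lower (4.4e-05 and 0.000538). With the decidual covariate 0 and 1 passed, with medians of -0.55 and -0.93, and camera called both lower (2.9e-08 and 0.00034).

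**Figure D2:**
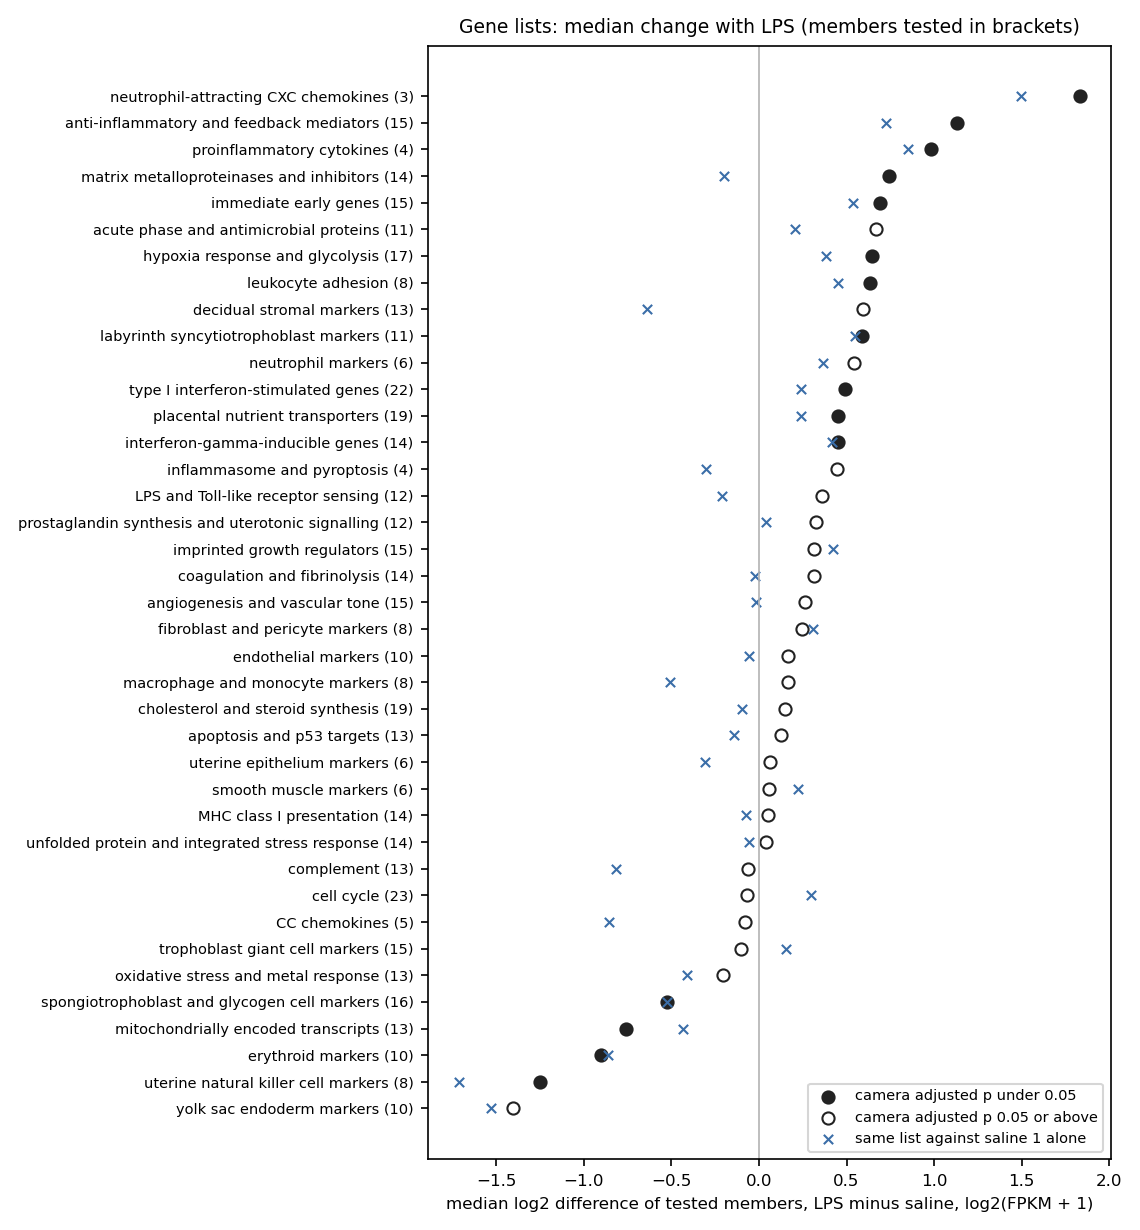
Median log2 difference (LPS minus saline, log2(FPKM + 1), horizontal axis) of the tested members of 39 gene lists, with the number of members in brackets. Filled circles have a camera adjusted p under 0.05, open circles do not, and crosses give the median against saline 1 alone: feedback mediators stand at 1.13 and 0.73, matrix metalloproteinases at 0.74 and -0.20, decidual markers at 0.60 and -0.64.

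Steroid, vascular and growth genes changed singly. Of 19 cholesterol and steroid synthesis genes 3 fell (3 adjusted over the list alone; camera adjusted p 0.380): Star, the steroid dehydrogenase gene Hsd3b6, from 4.29 ± 0.467 to 1.81 ± 0.637 FPKM, and Fdps, of the cholesterol pathway, from 26.7 ± 2.49 to 17.8 ± 1.33 FPKM. Of 15 angiogenesis and vascular tone genes 3 rose (3 adjusted over the list alone; camera adjusted p 0.125): the lipase inhibitor gene Angptl4, from 7.15 ± 0.236 to 15.8 ± 3.17 FPKM, the vasoconstrictor gene Edn1, from 1.61 ± 0.682 to 4.54 ± 1.07 FPKM, and the Notch ligand gene Dll4, from 2.15 ± 0.376 to 4.4 ± 0.99 FPKM. Of 15 imprinted growth regulators Igf2r rose (2 adjusted over the list alone; camera adjusted p 0.194), from 17.5 ± 4.97 to 34.1 ± 7.02 FPKM. Of 13 apoptosis genes Tnfrsf10b, a death receptor, rose (1 adjusted over the list alone; camera adjusted p 0.657), from 4.91 ± 1.41 to 15.1 ± 4.29 FPKM. Camera called the angiogenesis list higher without saline 1 (adjusted p 0.0400), and the imprinted list higher without saline 3 (0.0399), with quantile normalization (0.0398), against saline 1 alone (0.00109) and with the decidual covariate (0.00707).

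Other immune and stress lists did not pass as lists. Of 12 genes of LPS sensing the adaptor gene Ticam1 rose (2 adjusted over the list alone; camera adjusted p 0.129), from 6.55 ± 2.01 to 12.9 ± 1.19 FPKM. The LPS receptor genes Tlr4 and Cd14 did not pass, at 3.18 ± 2.89 against 3.03 ± 0.743 FPKM and 4.33 ± 4.63 against 8.64 ± 2.07 FPKM. Of 14 MHC class I genes the peptide-loading genes Tap1 and Tapbp rose (4 adjusted over the list alone; camera adjusted p 0.657), from 8.81 ± 2.02 to 17.4 ± 2.91 FPKM and from 68.5 ± 21.4 to 122 ± 13.1 FPKM. No member passed among 4 inflammasome genes (camera adjusted p 0.657), 11 acute phase genes (0.111), 13 complement genes (0.846), 14 coagulation genes (0.141), 12 prostaglandin and uterotonic genes (0.139), 13 oxidative stress genes (0.349), 14 unfolded protein response genes (0.887) and 23 cell cycle genes (0.186). Adjusted over the list alone, 2 coagulation genes and 1 oxidative stress gene were higher, 1 oxidative stress gene was lower, and the other 6 of these lists had 0. Without saline 1 camera called the LPS sensing (adjusted p 0.0341), acute phase (0.0413) and coagulation (0.0341) lists higher and the cell cycle list lower (0.0360). The acute phase list was also called higher without saline 2 (0.0251) or LPS 3 (0.0378) and with the trend removed (0.0256), coagulation higher with quantile normalization (0.0457), cell cycle lower without LPS 1 (0.0272), oxidative stress lower against saline 1 alone (0.0489), and complement lower against saline 1 alone (0.0013) and with the decidual covariate (0.00835). Median, mean and test differed in sign for complement, for the cholesterol list, for the unfolded protein list and for macrophage markers. Of the 7 MHC class II genes 2 were tested, Ctss and H2-DMa, at 28.6 ± 41.2 against 20.3 ± 9.06 FPKM and 1.82 ± 0.876 against 2.26 ± 0.379 FPKM; neither passed.

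The members with the highest levels of the lists without a change lay as follows in saline against LPS. Serpine1 and Tfpi, which limit fibrinolysis and clotting, were at 272 ± 166 against 328 ± 127 FPKM and 1641 ± 167 against 2038 ± 197 FPKM. The antimicrobial genes Slpi and Serpina3n were at 55.4 ± 86.2 against 66.7 ± 23.6 FPKM and 18 ± 12.4 against 26.8 ± 9.03 FPKM, and the complement regulators Serping1 and Cd55 at 67.9 ± 48.4 against 70.7 ± 33 FPKM and 20.5 ± 17.3 against 23.7 ± 4.69 FPKM. The inflammasome genes Nek7 and Gsdmd were at 21.1 ± 8.92 against 26.6 ± 5.29 FPKM and 5.91 ± 4.81 against 8.78 ± 1.34 FPKM. The metallothionein genes Mt1 and Mt2 were at 324 ± 211 against 259 ± 121 FPKM and 427 ± 199 against 357 ± 168 FPKM, and the chaperone genes Hspa5 and Hsp90b1 at 931 ± 114 against 816 ± 195 FPKM and 547 ± 56.6 against 501 ± 108 FPKM. The replication genes Rrm2 and Pcna were at 52.4 ± 68.1 against 115 ± 26.5 FPKM and 47.9 ± 11.8 against 28.6 ± 3.64 FPKM. Of the genes in this paragraph, Slpi, Serpina3n, Cd55, Nek7, Gsdmd, Rrm2 and Pcna passed without saline 1, as did 3296 of all 12241 tested genes.

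The genes tied to labor did not pass with all 7 libraries, and saline 1 stood far from the other saline libraries for Gja1 and Pgr. The prostaglandin synthase gene Ptgs2 was at 2.84 ± 0.572 FPKM in saline and 5.07 ± 1.56 in LPS (limma adjusted p 0.101), Ptges3 at 86.4 ± 4.87 FPKM in saline and 88 ± 5.36 in LPS, and the gap junction gene Gja1 at 43.2 ± 44 FPKM in saline and 65.8 ± 15.3 in LPS (0.20). The progesterone receptor gene Pgr was at 2.71 ± 3.53 FPKM in saline and 3.34 ± 1.18 in LPS (0.438). Without saline 1, Ptgs2, Gja1 and Pgr passed, at log2 changes of 0.75, 1.81 and 1.34 (limma adjusted p 0.0429, 0.000723 and 0.00756). They were among 3296 of 12241 tested genes that passed in that fit. Its controls were saline 2 and saline 3, the libraries low in decidual markers, of which Pgr is 1. Against saline 1 alone Gja1 was at -0.54 and Pgr at -0.88. In saline 1, 2 and 3 Gja1 was at 93.9, 20 and 15.6 FPKM and Pgr at 6.78, 0.937 and 0.433. Ptgs2 was at 3.47, 2.68 and 2.36 FPKM there, so saline 1 stood less apart for it. The oxytocin receptor gene Oxtr was not tested, at 0.0398 ± 0.0148 FPKM in saline and 0.068 ± 0.0136 in LPS.

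Among trophoblast markers, Syna and Pcdh12 rose. Of 11 tested labyrinth syncytiotrophoblast markers the syncytin gene Syna rose (5 adjusted over the list alone), from 24.8 ± 5.57 to 60.4 ± 14.7 FPKM, with a median of 0.59 (camera adjusted p 0.027, adjusted p 0.666 with an estimated correlation). Synb and the transcription factor gene Gcm1 did not pass, at 19.7 ± 5.73 against 34.3 ± 7.68 FPKM and 11.7 ± 3.64 against 19.4 ± 5.94 FPKM. This call ended without saline 1 (adjusted p 0.116) or LPS 1 (0.0946) and with fry (0.167). The 16 spongiotrophoblast and glycogen cell markers had a median of -0.53 (camera adjusted p 0.0276, adjusted p 0.666 with an estimated correlation), yet the 1 member that passed, the protocadherin gene Pcdh12, rose (1 adjusted over the list alone), from 22.6 ± 3.72 to 47.7 ± 5.82 FPKM. Tpbpa was at 21610 ± 8037 against 10924 ± 3498 FPKM (limma adjusted p 0.122). The call ended with median-ratio rescaling (0.105) and quantile normalization (0.853), with no low-value filter (0.0857), with fry (0.493), against saline 1 alone (0.424), with the length and GC trend removed (0.65), and without saline 2 (0.238), LPS 1 (0.0946) or LPS 3 (0.0855). None of 15 trophoblast giant cell markers passed (0 adjusted over the list alone; camera adjusted p 0.139): Prl3b1, placental lactogen II, was at 35437 ± 13064 against 22175 ± 5368 FPKM, and Ctsj at 8276 ± 2643 against 8054 ± 1504 FPKM. Camera called this list lower without saline 1 (adjusted p 0.0247) or LPS 2 (0.00581).

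Markers of other cell types differed between single libraries. Of 13 decidual stromal markers 0 passed (camera adjusted p 0.405), but Prl8a2, a decidual prolactin, was at 2248, 179 and 109 FPKM in saline 1, 2 and 3 and at 872 to 2029 in LPS. Cryab was at 70 ± 41.7 against 82.6 ± 25.8 FPKM. Camera called the decidual list higher without saline 1 (adjusted p 0.00794) and lower against saline 1 alone (0.00297). Yolk sac endoderm markers (0 of 10 passed, camera adjusted p 0.0691) were high in saline 3 and LPS 3: Afp was at 3441 and 5322 FPKM there, at 516 in saline 1 and at 25.2 to 67.2 in the other libraries. Apoa1 was at 486 ± 668 against 232 ± 446 FPKM. Camera called the yolk sac list lower without LPS 3 (2.0e-05) or saline 2 (0.00112). Macrophage markers (0 of 8 passed, camera adjusted p 0.636) included Csf1r at 164 ± 93.8 against 187 ± 39.1 FPKM and Cd68 at 91.9 ± 51.4 against 95.3 ± 33.5 FPKM, and were called lower against saline 1 alone (0.000943) and with the decidual covariate (0.00649). Uterine natural killer markers had a median of -1.25 with 0 of 8 passing (camera adjusted p 0.013, adjusted p 0.666 with an estimated correlation). The granzyme genes Gzmd and Gzmg were at 270.0 ± 146 against 97.9 ± 70.9 FPKM and 222 ± 126 against 84.1 ± 59.9 FPKM, and the call ended without saline 1 (adjusted p 0.0852) or saline 2 (0.0583) and with fry (0.398). Of 6 neutrophil markers S100a9 rose (3 adjusted over the list alone; camera adjusted p 0.0701); camera called the list higher without saline 1 (0.0483), saline 2 (0.0159) or LPS 3 (0.0354), with no low-value filter (0.00228) and with the trend removed (0.00496), and fry called it higher too (0.0301).

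Vascular and stromal lists did not pass, although single members rose. Of 10 endothelial markers the junction genes Esam and Cdh5 rose (2 higher and 1 lower adjusted over the list alone; camera adjusted p 0.657), from 90.7 ± 19.3 to 158 ± 15.7 FPKM and from 68.4 ± 22.3 to 134 ± 19.1 FPKM. Of 8 fibroblast and pericyte markers Pdgfrb rose (1 adjusted over the list alone; camera adjusted p 0.569), from 13 ± 3.71 to 33.8 ± 7.19 FPKM. Of 6 uterine epithelium markers Muc1 rose (1 adjusted over the list alone; camera adjusted p 0.939), from 41.9 ± 10.1 to 72.2 ± 11.9 FPKM. None of 6 smooth muscle markers passed (camera adjusted p 0.939): Smtn was at 25.9 ± 5.54 against 37.4 ± 6.38 FPKM, and Acta2 at 26.3 ± 9.71 against 29 ± 13.3 FPKM. The decidual, yolk sac, macrophage, natural killer and smooth muscle lists had 0 members past the threshold adjusted over the list alone. No T or B lymphocyte marker reached the filter: Cd79b was at 0.247 ± 0.0624 against 0.168 ± 0.11 FPKM, and Cd3g at 0.31 ± 0.175 against 0.0383 ± 0.0512 FPKM.

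**Figure D3:**
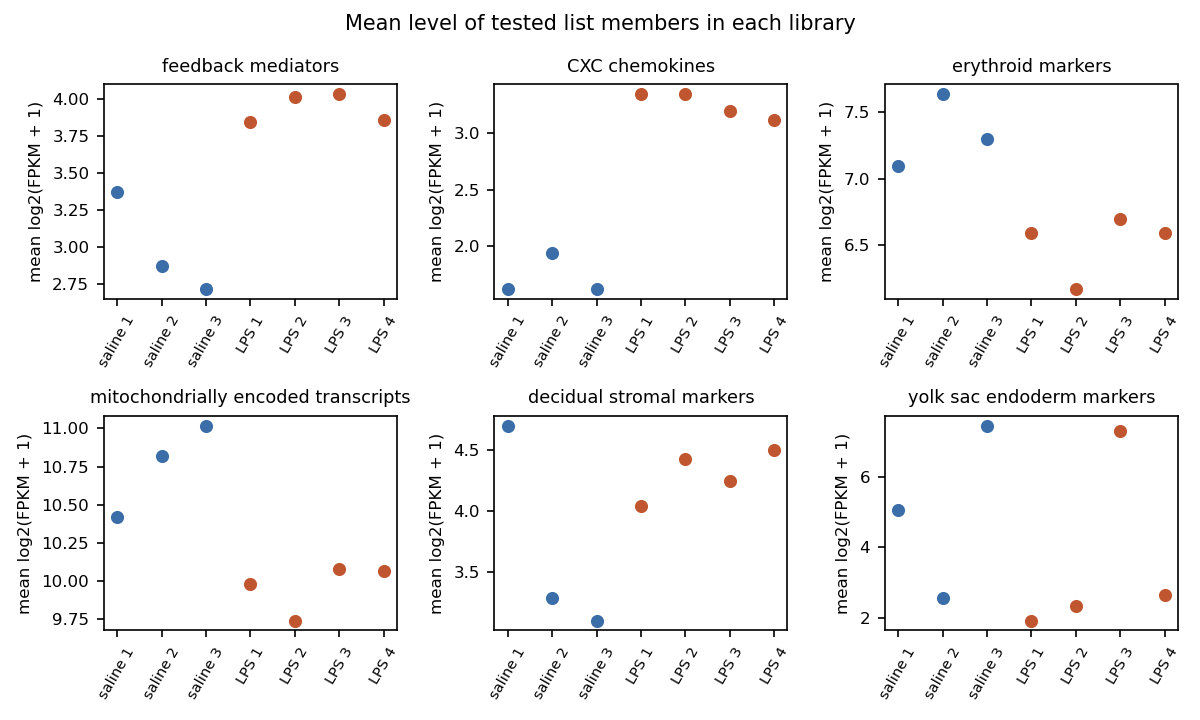
Mean log2(FPKM + 1) of the tested members of 6 lists (vertical axes, which do not start at 0) in each library, saline in blue and LPS in orange. Feedback mediators lie at 2.71 to 3.37 in saline and 3.84 to 4.03 in LPS, decidual markers at 3.29 and 3.10 in saline 2 and saline 3 against 4.04 to 4.70 in the other libraries, and yolk sac markers at 7.44 in saline 3 and 7.28 in LPS 3.

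The libraries were spread mainly along an axis that parted saline 2 and saline 3 from the rest. The first principal component held 49.4% of the variance, with saline 2 at 53.7, saline 3 at 34.4, saline 1 at -4.51 and the LPS libraries between -23.0 and -17.9. Saline 1 correlated at 0.973 and 0.974 with LPS 2 and LPS 4, and at 0.947 and 0.948 with saline 2 and saline 3 (Pearson, across genes). The feedback, CXC chemokine, immediate early, hypoxia and erythroid lists had camera adjusted p between 4.4e-05 and 0.00104 against saline 1 alone, where the spread comes from the LPS libraries only and the lone saline library is assumed to vary like them, and medians of 0.73, 1.5, 0.54, 0.38 and -0.86. Of their members 1, 1, 0, 1 and 0 passed there, and 6, 2, 3, 1 and 1 with the decidual covariate. Of the cytokine, interferon-gamma and labyrinth lists 0, 1 and 0 members passed against saline 1 alone and 0, 2 and 0 with the covariate, while their medians were 0.85, 0.42 and 0.55 against saline 1 alone and 1.01, 0.45 and 0.73 with the covariate. Camera called these lists higher in both fits, at adjusted p 0.00529, 0.000781 and 0.00297 against saline 1 alone and 0.0113, 0.000666 and 0.00524 with the covariate. Of the type I interferon and adhesion lists 0 and 2 members passed against saline 1 alone, with medians of 0.24 and 0.45, and 1 and 2 with the covariate, with medians of 0.37 and 0.54 (camera adjusted p 0.015 and 0.0425).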

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

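All explanation tests in this part, and the fits with the decidual covariate and with the length and GC trend removed, were chosen only after the results were seen.

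Of 146 values tested in the LPS group, 5 had a library far from the other 3, where chance alone gives about 1 in 20. Madcam1 in LPS 4 was at 6.475 FPKM, against 8.28, 8.65 and 8.62 in the other LPS libraries. Fdps in LPS 3 was at 19.8 FPKM, against 17.4, 17.2 and 16.9. Il10 in LPS 3 was at 0.085 FPKM, with the other LPS libraries listed at 0. The mean of the complement genes in LPS 1 was 2.37 on the log2(FPKM + 1) scale, against 2.86, 2.91 and 2.92. The mean of the yolk sac endoderm markers in LPS 3 was 7.28, against 1.92, 2.34 and 2.64.

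The rise of inflammatory genes was weighed over the 22 tested members of the cytokine, feedback and CXC chemokine lists, with a median log2 change of 1.07 (quartiles 0.61 and 1.49). Among them Csf3, Il1b and Cxcl2 met the filter through LPS libraries, so these medians can lean toward members high in LPS. With the decidual marker mean as a covariate the median was 0.94 (0.39 to 1.27), and with the length and GC trend removed it was 1.08 (0.66 to 1.48), which argues against tissue make-up as read by these markers, and against that trend, as the whole cause. Only 1 of the 35 splits of the libraries into 3 and 4, the real one, gave as many as 626 changed genes. The highest other gave 14. No split can reach a share below 1 in 35. Every other split mixes the groups, which widens its spread and lowers its count. Chance assignment is argued against for that count, but not excluded. A response of the placenta to LPS, the difference that the design names, remains as a hypothesis, found and tested on the same data. The LPS libraries are also labelled as preterm labor, so LPS exposure and labor cannot be told apart.

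The mitochondrial and erythroid lists were both lower. With the length and GC trend removed, the mitochondrial median moved from -0.76 (quartiles -0.91 and -0.61) to -0.05 (-0.23 and 0.05), so the call ended because the difference itself went to about 0, and a trend with transcript length and GC content is a candidate explanation. The erythroid median moved from -0.90 (quartiles -1.14 and -0.46) to -0.78 (-0.93 and -0.17), which argues against the trend as the whole cause there. Whether fewer red cells or a lower transcript level per cell lies behind the erythroid values was not tested.

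Saline 2 and saline 3 lay apart from the other 5 libraries. Of 13 decidual stromal markers, 7 were lower in both than in all 5 others, so less decidual tissue in these samples may contribute; but 25.1% of all tested genes were also lower in both, and no record of dissection is among the labels. A wrong label on saline 1 would need it to sit among the LPS libraries. It lay below all 4 of them in 17 of the 22 inflammatory members. Chance gives 4.4 if the genes are independent, which genes of a list need not be. These lists were also picked after their rise was seen, and Csf3, Il1b and Cxcl2 met the filter through LPS libraries. The count therefore speaks for the 22 members alone and cannot settle the label. The means of the CC chemokine, complement and inflammasome lists were instead highest in saline 1. The length and GC trend is argued against as the whole cause for the decidual difference alone. That difference had a median of -1.04 before the trend was removed and -1.27 (quartiles -2.01 and -0.28) after. For the separation over all genes the trend stays open. Across 12435 genes, saline 2 and 3 minus saline 1 had Spearman correlations of -0.29 with length and -0.31 with GC content. The nuclear RNAs Malat1 and Neat1, chosen after their values were seen, were also lower in saline 2 and saline 3. Malat1 was at 20.8 and 16.3 FPKM there, against 148 to 234 in the other 5 libraries. Neat1 was at 25.8 and 22.2 FPKM, against 107 to 163. What lies behind these values was not tested, and decidual markers alone do not cover it. The gestation stage, the sampled region and differences between pregnancies stay open and were not tested.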

How the results depend on the processing

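The fits without saline 2 and 3, with the decidual covariate, with the length and GC trend removed and with the Y-linked covariate, and the principal components without 1 library, were tests chosen after seeing the data; the other tests here were planned. The fit without saline 2 and 3 takes its spread from the LPS libraries and assumes that saline 1 varies like them. Where a value moved, the cause was not tested, except that fits without a library hold fewer samples and the fit with no low-value filter tests more genes. None of the 60 named genes that passed changed sign in any fit here, and their calls held for 60 without saline 1, 19 without saline 2, 25 without saline 3, and 16, 28, 21 and 24 without LPS 1, 2, 3 and 4. They held for 13 with no low-value filter, 28 with the decidual covariate, 36 with the replicate block and 45 with the trend removed. With the stricter filter 52 of them were still tested, and all of these held. In the other fits with all 7 libraries they held for 54 (Y-linked covariate) to 60 (library weights). Leaving out 1 library gave 34 to 3296 changed genes (3296, 64 and 111 without saline 1, 2 and 3; 34, 186, 93 and 94 without LPS 1 to 4), 31 to 2299 higher and 3 to 997 lower, and a first principal component of 42.7% (without saline 2) to 59.5% (without saline 1), with 55.3% without LPS 3, against 49.4%. No counting error can be given, since counts were not used here; the count-based alternatives (DESeq2, voom, RLE within edgeR, library size alone, and the second unit) were not run.

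Changed, higher and lower genes, against 626, 459 and 167, were 32, 31 and 1 at an adjusted p under 0.01; 225, 193 and 32 with at least 2-fold; 51, 45 and 6 with no low-value filter; 1035, 737 and 298 with robust eBayes; and 4894, 2977 and 1917 with library weights. They were 29, 17 and 12 with saline 2 and 3 left out and 144, 108 and 36 with the decidual covariate. Quantile normalization gave 1102 changed and 438 lower, median-ratio rescaling 295 lower and trend removal 94 lower. The replicate block gave 362 changed and 51 lower, but it also leaves out LPS 4, without which the fit with no block gave 94 and 10, so the move from 626 is not that of the block alone. In that fit the metalloproteinase list had an adjusted p of 0.147, against 0.103 without LPS 4 and with no block, and the yolk sac list 0.00285, against 0.155. The block rests on replicate numbers, and the labels do not say that these pair the libraries. Same-number correlations were -0.23, 0.23 and 0.45. Saline 2 and saline 3 correlated best with the LPS library of the same number, and saline 1 with LPS 2 (0.28). So few libraries cannot settle the pairing. Camera called 11 lists higher and 4 lower; an estimated correlation gave 0 and 0, and the lower lists numbered 8 with saline 2 and 3 left out, 7 with the decidual covariate, 2 with the trend removed and 2 with fry.

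Of the 40 tested named genes that did not pass, 18 passed without saline 1 (Nek7, Gsdmd, Slpi, Serpina3n, Cd55, Gja1, Ctss, Rrm2, Pcna, Prl8a2, Cryab, Smtn, Csf1r, Cxcl10, Ptgs2, Pgr, Cd14 and Synb), 24 with library weights, 4 with the replicate block, Tfpi and Pcna with quantile normalization, and Pcna with robust eBayes, the stricter filter or the Y-linked covariate. Named genes that did not pass changed sign as follows. With saline 2 and 3 left out: Ccl6 -2.03, Nek7 -0.25, Gsdmd -0.36, Slpi -1.27, Serpina3n -0.28, Serping1 -0.87, Cd55 -0.76, Serpine1 -0.57, Gja1 -0.54, Ctss -2.01, H2-DMa -0.24, Rrm2 -0.21, Ctsj 0.55, Prl8a2 -0.95, Cryab -0.56, Csf1r -0.55, Cd68 -0.72, Pgr -0.88, Tlr4 -0.9 and Cd14 -0.17; the metalloproteinase list turned (adjusted p 0.994, over its alternatives the highest) and the decidual list fell (0.00297). With the decidual covariate: Ccl6 -1.21, Nek7 -0.01, Slpi -0.02, Serping1 -0.45, Cd55 -0.24, Serpine1 -0.24, Ctss -1.06, H2-DMa -0.04, Ctsj 0.28, Cryab -0.25, Csf1r -0.21, Cd68 -0.46, Pgr -0.3 and Tlr4 -0.49. With the trend removed: Ccl2 0.21, Mt2 0.07, Mt1 0.06, Hsp90b1 0.03 and Ctsj 0.43. With library weights: Ccl2 0.7, Mt2 0.29, Mt1 0.5 and Acta2 -0.14. With the block: Ccl6 -0.13, Ctsj 0.08 and Cd68 -0.01. With quantile normalization: Hsp90b1 0.06 and Ctsj 0.8; with median-ratio rescaling: Ptges3 -0.07. Without saline 1: Ccl2 0.04, Ptges3 -0.02, Mt2 0.09, Mt1 0.29 and Acta2 -0.23. Without saline 2: Ccl6 -0.57, Ccl2 0.01, Ctss -0.15 and Ctsj 0.21. Without saline 3: Ccl6 -0.2, Serping1 -0.38, Ctss -0.12, Ctsj 0.06, Cd68 -0.21, Afp 0.09 and Tlr4 -0.29. Without LPS 1, Ctsj 0.06; without LPS 2, Serping1 -0.05 and Cd68 -0.04; without LPS 3, Acta2 -0.15; without LPS 4, Ccl6 -0.13, Ctsj 0.08 and Cd68 -0.01. The other end over the fits without 1 library was 1.25 for Ccl6, 0.76 for Serping1, 1.73 for Ctss and 0.69 for Tlr4 (without saline 1), -0.83 for Ccl2, -0.62 for Mt2 and -0.68 for Mt1 (without saline 3), 0.35 for Acta2 (without LPS 2) and -3.15 for Afp (without LPS 3).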

Other observations

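Apart from the fetal sex transcripts, fixed in advance, and Adora2b and Ctss, which the rule for named genes picked, the genes in this part were chosen after their values were seen, and no further tests were run on them. Among the 31 genes past the threshold in each of the 7 fits without 1 library, 17 stood in no fixed list. Relb and Nfkb2, which encode subunits of the noncanonical NF-kB pathway, were at 3.56 ± 1.4 FPKM in saline and 15.5 ± 2.84 in LPS (log2 change 1.88, limma adjusted p 0.00567) and 3.3 ± 1.33 FPKM in saline and 12.3 ± 2.04 in LPS (1.66, 0.00876), higher in 4 of 4 LPS than in 3 of 3 saline libraries. Stat3 and Jak3, of cytokine receptor signalling, were at 17.1 ± 4.16 FPKM in saline and 52.4 ± 3.21 in LPS (1.58, 0.0051) and 3.92 ± 0.579 FPKM in saline and 12.8 ± 3.01 in LPS (1.47, 0.00934). Nod2, an intracellular sensor of bacterial cell wall fragments, was at 0.646 ± 0.0612 FPKM in saline and 3.73 ± 0.958 in LPS (1.5, 0.00876), and Litaf, an LPS-induced gene, at 72.8 ± 9.03 FPKM in saline and 151 ± 7.57 in LPS (1.04, 0.00678).

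Genes of other functions stood among the 17 too. Phactr1, a regulator of actin, was at 30.1 ± 2.6 FPKM in saline and 96 ± 8.95 in LPS, Proser2 at 15.7 ± 1.06 FPKM in saline and 41.5 ± 2.38 in LPS, and the metallopeptidase gene Amz1 at 6.6 ± 0.688 FPKM in saline and 16.8 ± 1.71 in LPS. Insm1, a transcription factor of neuroendocrine cells, was at 0.0506 ± 0.0123 FPKM in saline and 2.01 ± 0.448 in LPS, and the growth factor receptor gene Fgfr2 at 21.6 ± 2.78 FPKM in saline and 54.6 ± 6.04 in LPS. The remaining members were Adora2b, B3gnt7, Cnnm2, Slc30a2, Svep1 and Tcf4.

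The fetal sex transcripts fixed in advance were not tested. Ddx3y was at 21.8 FPKM in saline 2, 13.3 in LPS 2 and 14.8 in LPS 3, at 0.042 in saline 3 and at 0 in saline 1, LPS 1 and LPS 4. Xist was at 43.8, 0.248 and 17.9 FPKM in saline 1 to 3 and at 88.0, 13, 5.20 and 46.0 in LPS 1 to 4.

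The nuclear long noncoding RNAs Malat1 and Neat1 were at 20.8 and 25.8 FPKM in saline 2 and at 16.3 and 22.2 in saline 3, against 148 to 234 and 107 to 163 in the other 5 libraries. Macrophage-expressed genes were highest in saline 1: Lyz2 was at 212 FPKM there and at 7.70 to 49.5 elsewhere, Ctss at 76.2 against 4.66 to 27.8, and Tyrobp at 28 against 4.07 to 7.49.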
